A study of Penicillium decumbens with 6 samples.

How the data were processed

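Tag libraries from 6 cultures of Penicillium decumbens were analysed, 1 for each of 2 strains in 3 media. Per the labels' protocols, mRNA was taken on oligo(dT) beads and made into double-stranded cDNA, which was cut at CATG with NlaIII. An adapter was joined to that end, MmeI cut 17 bases further on, and the products were amplified and sequenced. Each file gives tags of 21 bases with their counts, per the file headers raw copy numbers that the authors did not normalise. The authors also deposited a TPM for each tag. It equals the copies per 1000000 copies (CPM) in the same file to within 0.005, with no transcript length in it, and was used only for this check. The lowest count in any file is 2 copies, so a tag that is not listed had 0 or 1 copies. The base caller, the trimming and other filters are not given in the sources used here. PCR copies are not independent molecules, and with no molecular identifiers the intervals cover counting error only.

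Library totals were 2951973 copies in 114-2 glucose, 3613874 in 114-2 cellulose, 2941173 in 114-2 cellulose-wheat bran, 3527809 in JU-A10-T glucose, 3541622 in JU-A10-T cellulose and 3635528 in JU-A10-T cellulose-wheat bran. For a fold against a library where a tag is not listed, the tag was set at 4.74 copies in that library, the one-sided 95% upper limit for 1 copy (1.26 to 1.95 CPM after scaling), and the fold is given as at least that size.

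The features tested were the tags. The tests, the samples in each, the alternatives and the rule for naming tags were fixed before the data were examined. Tags with 5 or more CPM in at least 2 libraries (20794 tags) were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, on strain and medium as additive terms. This leaves 2 residual degrees of freedom, and any difference of the medium response between the strains counts as error. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. They measure the spread between these 6 libraries only. For single pairs of libraries no test was made. There a tag counted as higher or lower if its ratio of scaled CPM, each plus 1, was at least 4-fold, with at least 20 CPM in the higher library. Overlaps between strains use different libraries on each side and are set beside the overlap of independent lists. Another scaling moved the median log2 change of all tags in the additive fits by up to -0.164 with DESeq2 size factors and 0.171 with library totals.

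The tags named were, for each tested comparison and direction, the 8 with the largest change among those past the test with a mean of at least 10 CPM and at least 2-fold in the same direction in every pair. Where fewer passed, as in every comparison of media, the list was filled with tags not past the test, by the smallest ratio over the pairs, with 20 CPM in the higher library of each. For each pair of libraries the 4 largest ratios in each direction were taken. The few largest are printed. The 1-base pairs, the tags common to both strains and the tag families were chosen after seeing the data.

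The edgeR step was tested on simulated counts. For cellulose against glucose with 20794 tags and a dispersion of 0.05 it found 95% of the tags changed 4-fold and 100% of those changed 16-fold, with 13 false calls. For JU-A10-T against 114-2 at a dispersion of 0.5 it found 41% of the tags changed 16-fold and 0% of those changed 4-fold. The search for 1-base pairs found 50 of 50 planted pairs and 0 others.

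Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals, no filter, a filter of 20 CPM, each library left out, an offset of 5 and a 2-fold rule. Chosen after seeing the data were merging tags with a 1-base neighbour at least 20 times as abundant, merging the 1-base strain pairs, and leaving out tags with a second CATG or that begin with CATGTCGGAC. No reference genome was used, so the planned lists of genes, the assignment of tags to genes and the alternatives built on it were not run. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.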

Results

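Messenger RNA tags were counted in 2 strains of the filamentous fungus Penicillium decumbens, each grown in 3 media. Strain 114-2 is a wild-type cellulose degrader, and JU-A10-T is a cellulase-hyperproducing mutant obtained from it. The glucose medium held 2% glucose and the cultures grew in it for 41 h. For the cellulose medium, mycelium was grown for 39 h in glucose and then for 2 h with 2% cellulose. The cellulose-wheat bran medium held 1% cellulose and 1% wheat bran, again for 41 h. Each strain and medium gave 1 library, so no strain and medium has a replicate. A tag is the CATG site of the enzyme NlaIII and the 17 bases after it, and stands for a transcript that carries it. No reference genome was used here, so tags are given by sequence and carry no gene names. Library totals ran from 2941173 copies in 114-2 cellulose-wheat bran to 3635528 in JU-A10-T cellulose-wheat bran. The 6 libraries held 199664 distinct tags, of which 19599 were listed in all 6 and made up 81.3% of the copies. Levels are in CPM, the copies of a tag per 1000000 copies after scaling of the library size, and intervals on ratios are exact 95% conditional binomial intervals that cover counting error only.

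The libraries of JU-A10-T resembled one another, and in 114-2 the cellulose library was unlike the other 2. Across 20794 tags, which are not independent replicates, the levels in JU-A10-T cellulose and cellulose-wheat bran had a Pearson r of 0.829, and r was 0.769 for glucose and cellulose and 0.751 for glucose and cellulose-wheat bran. In 114-2, glucose and cellulose-wheat bran had an r of 0.781, and cellulose had an r of 0.475 with glucose and 0.569 with cellulose-wheat bran. The strains were closest in cellulose, with an r of 0.668, against 0.371 in cellulose-wheat bran and 0.230 in glucose. Tags that hold a second CATG made up 3.43% of the copies in 114-2 glucose and 1.76% in 114-2 cellulose-wheat bran, and from 0.352% to 0.393% in the other 4 libraries. The 114-2 glucose and cellulose-wheat bran libraries therefore stood apart in tag composition as well as in tag levels, and every comparison below that uses one of them carries that difference.

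**Figure D1:**
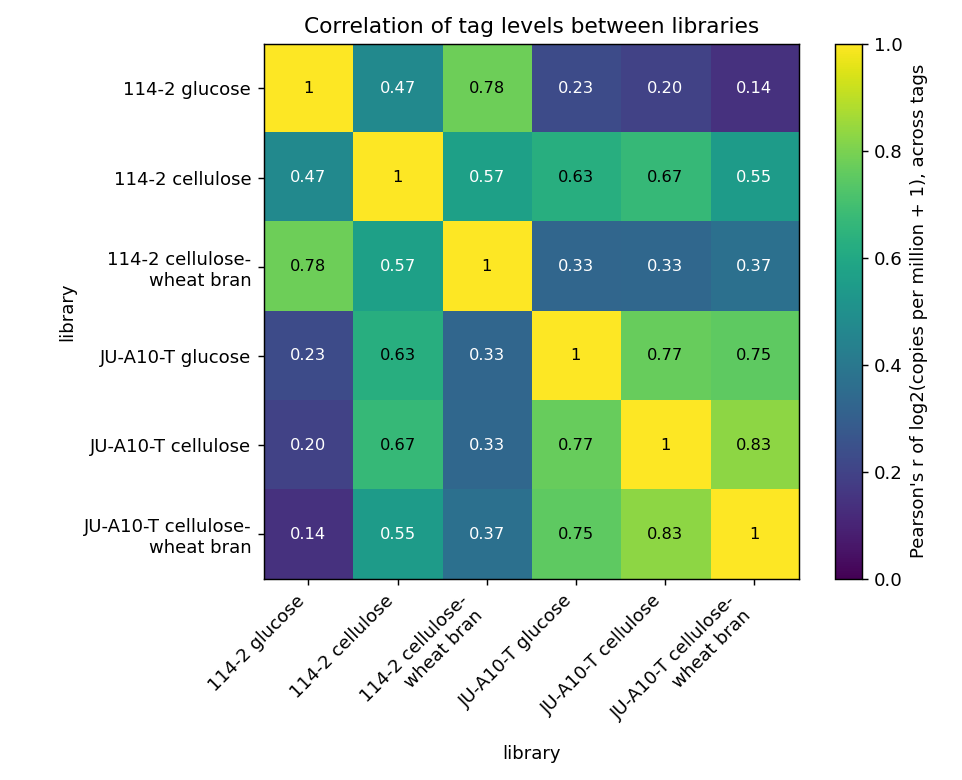
Pearson's r of log2(CPM + 1) across 20794 tags for each pair of the 6 libraries, on both axes in the same order, with the colour scale from 0 to 1. The 3 JU-A10-T libraries lie between 0.751 and 0.829 with one another, and 114-2 glucose has an r of 0.230 with JU-A10-T glucose.

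**Figure D2:**
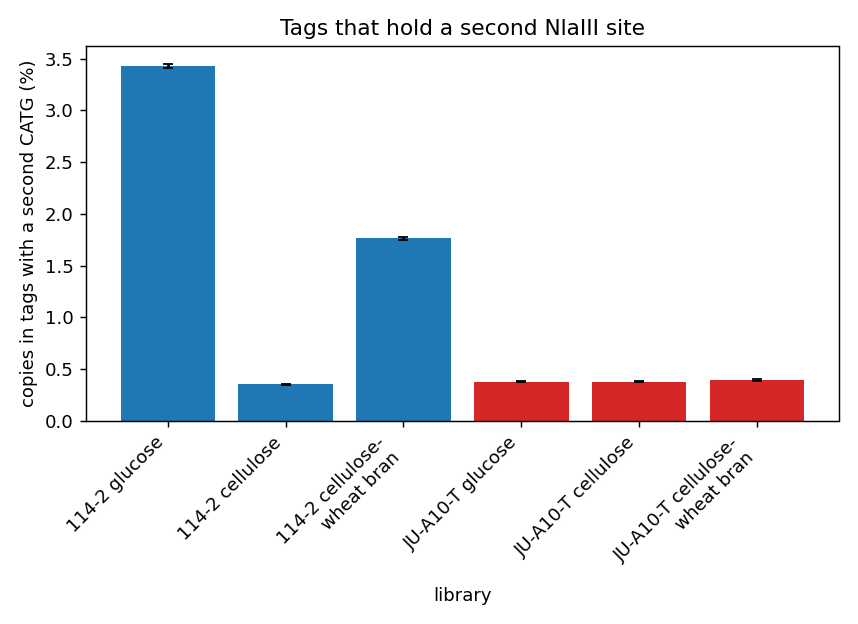
Percent of the copies of each library (vertical axis, from 0) that fall in tags with a second CATG, with exact 95% binomial intervals as error bars. 114-2 glucose reaches 3.43% and 114-2 cellulose-wheat bran 1.76%, and the other 4 libraries stay at or below 0.393%.

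The comparison of cellulose with glucose asked which transcripts differ after a 2 h exposure to cellulose. Loss of glucose and the move between media changed together with that exposure and cannot be told apart from it. The tag CATGGACACCTCCCGTAACGG stood at 1.64 CPM in 114-2 glucose and 469.9 in 114-2 cellulose, a ratio of 286 (112 to 1051). In JU-A10-T the same tag went from 325.8 in glucose to 18650 in cellulose, a ratio of 57.2 (54.1 to 60.6). The tag CATGGCTCAAAGAACCACTTT was 252-fold higher in 114-2 cellulose than in glucose (98.1 to 925) and 59.8-fold higher in JU-A10-T (53.4 to 67.3). The tag CATGGCTCAGCACTGGGGACA was not listed in 114-2 glucose and at least 166-fold higher in 114-2 cellulose, and was 73.2-fold higher in JU-A10-T (65.8 to 81.7). Among tags lower in cellulose, CATGAGGGGGACATTGTGGAA was 70.3-fold lower in 114-2 (47.4 to 109) and 34.3-fold lower in JU-A10-T (19.9 to 65.0). CATGATATGATTATAACGATA was 40.3-fold lower in 114-2 (32.4 to 50.9) and 14.6-fold lower in JU-A10-T (10.1 to 21.7). Of the 16 tags taken by the naming rule for this comparison, 3 of those lower in cellulose hold a second CATG, the feature that was most frequent in 114-2 glucose.

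By the rule of size, 1568 tags were at least 4-fold higher and 3739 at least 4-fold lower in cellulose than in glucose in 114-2, and 1258 were higher and 933 lower in JU-A10-T. Scaling by library totals alone gave 1999 higher and 2941 lower in 114-2, where the median log2 ratio moved from -0.39 to 0.27. Of the 5593 tags considered in both strains, 191 were higher in both, where independent lists would share 143, and 77 were lower in both, where 29.2 would be shared. The log2 ratios of the strains had an r of 0.12 across these tags. With strain in the model, edgeR's quasi-likelihood test called 0 tags after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 it gave 850 higher and 1571 lower tags. With no difference 1040 would be expected over both directions together, in this and each later comparison of the 20794 tags. DESeq2 called 135 higher and 239 lower. Without the JU-A10-T cellulose library the edgeR test called 606 and 1556, and without the 114-2 cellulose library 78 and 15. In simulated counts for this comparison with 20794 tags and a dispersion of 0.5, close to the 0.503 of the data, the test found 1% of tags changed 16-fold and 0% of those changed 4-fold, which limits what a count of 0 shows.

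The comparison of cellulose-wheat bran with glucose set media that were inoculated directly and grown for the same time. CATGGCTCAAAGAACCACTTT was again higher, by 293-fold in 114-2 (114 to 1076) and by 108-fold in JU-A10-T (96.1 to 121). CATGTTTGATGCAATTTGACG went from 2.87 to 512.9 CPM in 114-2, a ratio of 178 (86.4 to 445), and from 11.4 to 1561 in JU-A10-T, a ratio of 137 (101 to 189). CATGGTTGTCTTATCAGCAAA was not listed in 114-2 glucose and at least 75.8-fold higher in 114-2 cellulose-wheat bran, and was 187-fold higher in JU-A10-T (147 to 241). It differs only in its last base from CATGGTTGTCTTATCAGCAAC, which stood at 144.4 CPM against its 147.7 in 114-2 cellulose-wheat bran and at 4481 against 3370 in JU-A10-T cellulose-wheat bran. The C-ending tag was at least 74.1-fold higher in 114-2 and 69.7-fold higher in JU-A10-T (61.4 to 79.5). The tags were not assigned to transcripts. The tags lower in cellulose-wheat bran were nearly unlisted there in both strains. CATGTACTTCAATGTCTATGT stood at 1793 CPM in 114-2 glucose and 3.31 in cellulose-wheat bran, and at 2880 and 1.92 in JU-A10-T, which made it 542-fold (303 to 1087) and 1501-fold (728 to 3733) lower. CATGAGCTGTTCGGCCGTTGC was 946-fold lower in 114-2 (405 to 2914) and 1623-fold lower in JU-A10-T (555 to 7871).

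By the rule of size, 542 tags were higher and 2539 lower in cellulose-wheat bran than in glucose in 114-2, and 1126 were higher and 1055 lower in JU-A10-T. Library totals alone gave 910 higher and 1759 lower in 114-2. Of 4609 tags considered in both strains, 115 were higher in both, where independent lists would share 27.6, and 119 were lower in both, where 24.2 would be shared. The additive edgeR test called 0 tags, with 485 higher and 756 lower at an unadjusted p under 0.05, and DESeq2 called 111 and 181. The edgeR calls were 18 and 96 without 114-2 glucose, 196 and 316 without 114-2 cellulose, and 149 and 272 without JU-A10-T cellulose.

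In both strains, 32 tags were at least 4-fold higher in each of the cellulose-containing media than in glucose. Their median level in 114-2 was 3.08 CPM in glucose, 56.5 in cellulose and 118 in cellulose-wheat bran. In JU-A10-T the medians were 32.3, 788 and 1127. Together they took 0.557% of the copies in 114-2 cellulose and 6.41% in JU-A10-T cellulose, and 0.858% and 7.92% in cellulose-wheat bran. The JU-A10-T level was above the 114-2 level for 31 of the 32 tags in cellulose, 30 in cellulose-wheat bran and 29 in glucose. The median ratio of JU-A10-T to 114-2 was 12.8 in cellulose and 7.86 in cellulose-wheat bran. None of the 32 holds a second CATG, which says little, as only 2.00% of all tags tested hold one. Independent lists would share 4.13 tags. Another 32 tags were at least 4-fold lower in both media in both strains, of which 4 hold a second CATG and another 4 begin with CATGTCGGAC, a start described with the single pairs. This second set is smaller than the 80.9 tags that independent lists of 518 and 2283 would share. Neither this count nor the 4.13 decides, as both are over all tags at 20 CPM in any library. Many of those were hardly present in JU-A10-T. Among tags considered in both strains, those lower in both exceeded independent lists. They numbered 77 against 29.2 in cellulose and 119 against 24.2 in cellulose-wheat bran. Both sets of 32 tags were chosen on their medium ratios in both strains. That favours low glucose levels in the first set and high ones in the second.

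**Figure D3:**
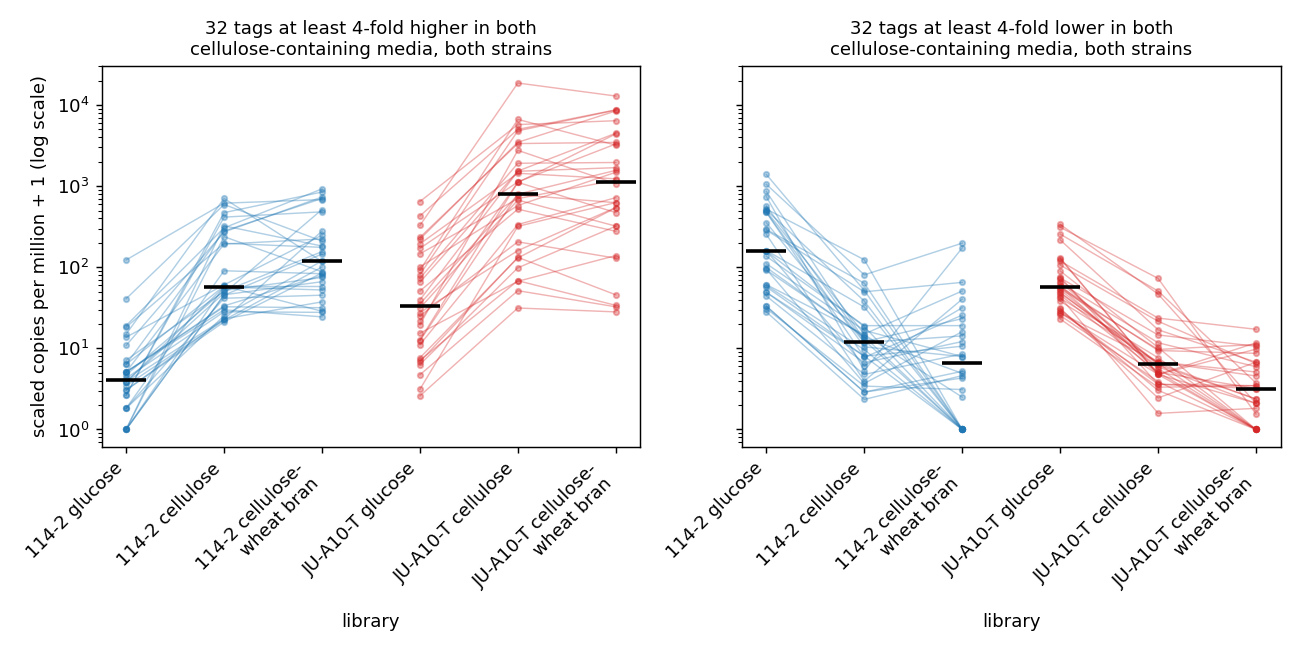
Levels of the 32 tags at least 4-fold higher (left) and the 32 at least 4-fold lower (right) in both cellulose-containing media in both strains, as scaled CPM + 1 on a log axis, by library. Each line is 1 tag, blue for 114-2 and red for JU-A10-T, and black bars are medians. The median of the left set is 118 in 114-2 cellulose-wheat bran and 1127 in JU-A10-T cellulose-wheat bran.

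Between the cellulose-containing media, medium and time in the medium changed together. CATGTACTTCAATGTCTATGT was 1466-fold lower in cellulose-wheat bran than in cellulose in 114-2 (819 to 2938) and 853-fold lower in JU-A10-T (414 to 2122). CATGAGCTGTTCGGCCGTTGC was 474-fold lower in 114-2 (203 to 1462) and 502-fold lower in JU-A10-T (171 to 2435). CATGCAGGAGATGATTGAATA was 144-fold higher in cellulose-wheat bran in 114-2 (85.7 to 264) and 26.8-fold higher in JU-A10-T (19.0 to 39.2). CATGGCCCTCGAGCACCTCGG was 111-fold higher in 114-2 (76.4 to 169) and 40.2-fold higher in JU-A10-T (19.3 to 101). By the rule of size, 1585 tags were higher and 1403 lower in 114-2, and 703 were higher and 788 lower in JU-A10-T. Of 5509 tags considered in both strains, 166 were higher in both, where independent lists would share 22.7, and 168 were lower in both, where 72.9 would be shared. The additive edgeR test called 0 tags, with 1522 higher and 781 lower at an unadjusted p under 0.05, and DESeq2 called 146 and 172. The edgeR calls were 30 and 84 without 114-2 glucose, 15 and 135 without 114-2 cellulose, and 968 and 774 without JU-A10-T cellulose.

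The comparison of JU-A10-T with 114-2 asked which transcripts differ between the mutant and its ancestor whatever the medium. The additive edgeR test called 838 tags higher and 1385 lower in JU-A10-T at an adjusted p under 0.05. CATGGGGTTTGGGGGAGAATG, the tag with the largest fitted change upward, stood at 1878, 5080 and 990.7 CPM in JU-A10-T glucose, cellulose and cellulose-wheat bran and was not listed in any 114-2 library. It was at least 964-fold, 3974-fold and 694-fold higher in the 3 media (edgeR adjusted p = 0.0145). CATGTTCAAGAGCCCTTGATT, with the same adjusted p of 0.0145 by edgeR, was at least 658-fold, 325-fold and 274-fold higher. Among the tags lower in JU-A10-T, CATGGTCCCATTGAAGGTTGA stood at 2113, 1925 and 1335 CPM in the 3 media in 114-2 and was not listed in JU-A10-T, so it was at least 1678-fold, 1401-fold and 1026-fold lower (edgeR adjusted p = 0.0145). CATGCCACGGAGCAAATTGCC was at least 554-fold, 1042-fold and 2389-fold lower, with the same edgeR adjusted p of 0.0145. All 16 tags taken by the naming rule passed the test.

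Of the 838 tags called higher, 535 were not listed in any 114-2 library, and of the 1385 called lower, 794 were not listed in any JU-A10-T library. The strains were closest in cellulose. There, 60.0% of the tags called higher and 30.8% of those called lower met the rule of size in the direction of the call. That rule needs 20 CPM in the higher library, so called tags below that level in cellulose count as not meeting it. A second CATG was present in 6.71% of the tags called lower, in 0.239% of those called higher and in 2.00% of all tags tested. The count rested on single libraries. Without JU-A10-T glucose edgeR called 0 tags, with 1441 higher and 2429 lower at an unadjusted p under 0.05. It called 2651 higher and 4038 lower without 114-2 cellulose, and 2662 and 3783 without JU-A10-T cellulose. It called 405 and 537 without 114-2 cellulose-wheat bran, 414 and 667 without JU-A10-T cellulose-wheat bran, and 844 and 815 without 114-2 glucose. Leaving out both 114-2 libraries that stood apart would leave 4 libraries for 4 coefficients and no test.

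Within single media, the rule of size gave 2237 tags higher and 4356 lower in JU-A10-T than in 114-2 in glucose, 1107 and 1045 in cellulose, and 1783 and 1999 in cellulose-wheat bran. In glucose, library totals alone gave 2747 and 3413. The difference was at least 4-fold in the same direction in all 3 media for 247 tags higher and 281 lower in JU-A10-T. CATGTTGTGCCTTTGTTTTTG stood at 7922 CPM in 114-2 glucose and 1.33 in JU-A10-T glucose, but at 6.74 and 12.2 in cellulose. CATGGGGTTTCTTGGTCTCGG stood at 6069 in 114-2 cellulose and 2.32 in JU-A10-T cellulose. CATGCGCATCAAATGCAAAGT was not listed in 114-2 cellulose-wheat bran and stood at 8020 in JU-A10-T cellulose-wheat bran, at least 5620-fold higher. Several of the largest single-pair ratios in JU-A10-T belonged to tags that begin with CATGTCGGAC, such as CATGTCGGACTGTAACAGTCT at 5077 in JU-A10-T glucose and listed in no other library. Tags with this start made up 2.53% of the copies in JU-A10-T glucose (exact 95% binomial interval 2.52 to 2.55) and from 0.156% to 0.645% in the other libraries.

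Some tags of one strain had a counterpart in the other that differed by 1 base. CPM in this paragraph are on library totals, without scaling. At 5 or more CPM in every library of one strain and under 1 in every library of the other, 376 tags belonged to 114-2 and 398 to JU-A10-T. Among these, 93 pairs differed at a single base, against 10 pairs within the strains, from about as many combinations of tags (149503 within and 149648 between). With positions counted from 1 at the 5′ end of the tag and the 114-2 base first, CATGGTCCAGATTCAATCGGT and CATGGTCCAAATTCAATCGGT form the pair G10A. The 114-2 form averaged 274.5 CPM in 114-2 and the JU-A10-T form 273.3 in JU-A10-T. Transitions made up 66 of the 93 differences and transversions 27. The median log2 ratio of the JU-A10-T form to the 114-2 form was 0.0057, and 90 of the 93 pairs lay within 4-fold. The 93 JU-A10-T forms were all among the tags called higher, and 92 of the 114-2 forms among those called lower. Their choice, at 5 or more CPM in one strain and under 1 in the other, favours these calls. With the forms of each pair counted together, an alternative chosen after seeing the data, 705 tags were called higher and 1241 lower.

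**Figure D4:**
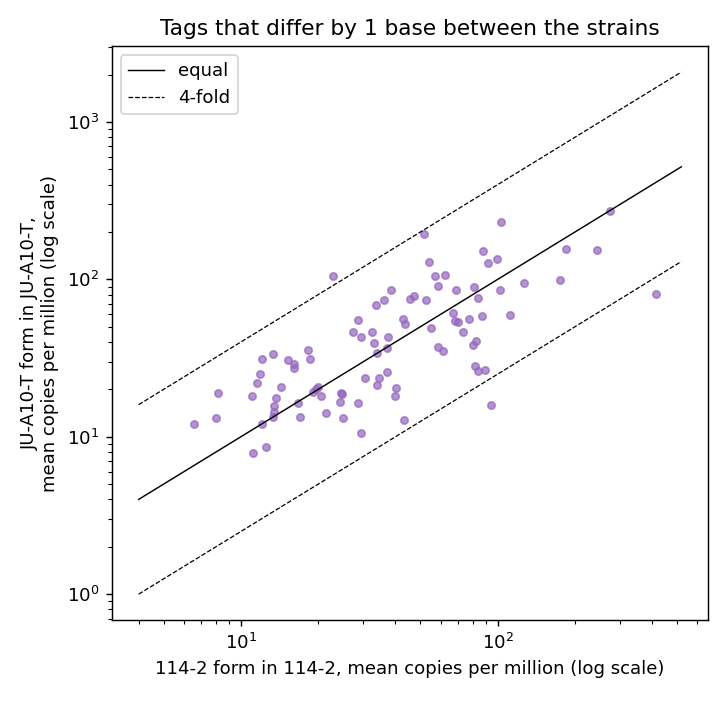
Mean CPM over the 3 media of the 114-2 form in 114-2 (horizontal) and of the JU-A10-T form in JU-A10-T (vertical) for the 93 pairs of tags that differ by 1 base, both on log axes. CPM here are on library totals, without scaling. Each point is 1 pair, the solid line marks equal levels and the dashed lines 4-fold, and 90 of the 93 points lie within the dashed lines.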

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

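The tests of NlaIII digestion in all libraries, of strain labels and of transfer to cellulose were chosen after the result was seen, and that of library depth before. Tags that changed at least 4-fold in opposite directions in the strains were noted for each comparison of media. This difference between the strains was not tested, because each strain and medium has 1 library. For cellulose against glucose there were 128 such tags, which is 32.3% of those changed in both strains. There were 36, or 13.3%, for cellulose-wheat bran against glucose, and 23, or 6.44%, for cellulose-wheat bran against cellulose. For cellulose against glucose, 92 were higher in 114-2 and lower in JU-A10-T, where independent lists would share 87.3, and 36 were the other way, where 47.8 would be shared. For the other comparisons the counts lay below those of independent lists: 18 and 18 against 24.4 and 27.2 for cellulose-wheat bran against glucose, and 19 and 4 against 38.6 and 42.9 for cellulose-wheat bran against cellulose.

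The 114-2 glucose and cellulose-wheat bran libraries stood apart from the other 4. Library depth is argued against, since r between the strains stayed 0.435 lower in glucose than in cellulose with all libraries thinned to one total, and so is a wrong strain label, since the other strain's form made up at most 0.0963% of the copies at 1-base pairs defined without the library. Transfer to cellulose stays open, since r of cellulose-wheat bran with cellulose was 0.0788 above that with glucose in JU-A10-T, the other way round from 114-2, but in single libraries. Incomplete NlaIII digestion stays open too: the upstream tag was expected to have a higher share in 114-2 glucose than in each of the other 4 libraries in over 50% of 409 chains of a tag and the tag at its second CATG, and had it in 47.4%, a count that decides nothing because 159 upstream tags begin with the adapter sequence CATGTCCGACATG and are at 0 in 114-2 glucose. The other 250 chains gave 77.6% (exact 95% binomial interval 71.9 to 82.6), which goes with incomplete digestion. The 166 chains whose upstream tag reached 5% in some library gave 91.0%. That filter favours this outcome, since 158 chains were over 5% in 114-2 glucose itself. Both subsets were chosen after the first count missed its bound, and a difference in the 114-2 cultures was not tested.

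Of the 10 splits of the 6 libraries into 3 and 3, the strains gave 2223 calls and the highest other split gave 0, and only 1 split, that of the strains, gave as many. Only 3 of the 9 other splits part the libraries of every medium as the strains do, and the other 6 rest on 1 medium each. With 10 splits no share under 0.05 can be had. The fits of the other splits held no strain term, so the strain difference counted as error in them. That favours 0 calls there, and the comparison decides nothing about the strain calls.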

How the results depend on the processing

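In the additive fits, the tool, the filter and single libraries moved counts of calls by more than 1.5 times, and the other scalings did not. With no filter the edgeR test called 132 higher and 265 lower tags for cellulose against glucose, 95 and 184 for cellulose-wheat bran against glucose, 77 and 194 for cellulose-wheat bran against cellulose, and 1422 and 2366 for JU-A10-T against 114-2. DESeq2 called 135 and 239, 111 and 181, 146 and 172, and 1767 and 2631. The filter of 20 CPM gave 446 and 641 between the strains. Leaving out 1 library, with 1 residual degree of freedom, gave 0 to 606 higher and 0 to 1556 lower for cellulose against glucose, 0 to 196 and 0 to 316 for cellulose-wheat bran against glucose, 0 to 968 and 0 to 774 for cellulose-wheat bran against cellulose, and 0 to 2662 and 0 to 4038 between the strains. The cause was not tested.

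For single pairs, the 2-fold rule by its construction gave more tags. In 114-2 it gave 3061 higher in cellulose than glucose, 1568 higher in cellulose-wheat bran than glucose, and 2787 lower in cellulose-wheat bran than cellulose. In JU-A10-T it gave 2550 higher and 2274 lower in cellulose than glucose, 2363 and 2324 in cellulose-wheat bran than glucose, and 1762 and 2021 in cellulose-wheat bran than cellulose. Between the strains it gave 3486 higher in JU-A10-T in glucose, 2077 higher and 2038 lower in cellulose, and 3099 higher in cellulose-wheat bran. An offset of 5 gave 612 lower in JU-A10-T cellulose than glucose and 449 higher in JU-A10-T cellulose-wheat bran than cellulose. Library totals gave 910 higher in 114-2 cellulose-wheat bran than glucose. The other single-pair counts stayed within 1.5 times. Over the single pairs and the additive fits together, 159 counts stayed within that bound, unchanged ones included, and 61 did not.

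No named tag turned its direction in any fit. For the named tags of single pairs, 95 of 144 log2 ratios under library totals or an offset of 5 moved beyond their counting interval, and 49 did not. Of 224 values for the named strain tags, 207 stayed past the test. Of the 17 that did not, 16 came without JU-A10-T glucose and 1 with 1-base neighbours merged. Of the named tags of the media, 52, 78 and 57 values passed the test under alternatives, in the order of the comparisons above. Setting tags counted once to 0 moves nothing, since the files list none. The alternatives that need gene sites (the site nearest the 3′ end, 1 mismatch, other extensions) and the gene lists were not run. Depth limits a tag that is not listed to between 1.26 CPM in JU-A10-T glucose and 1.95 in 114-2 glucose.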

Other observations

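The tests of base differences and of sequencing errors were chosen after the result was seen, and those of near-identical genes and of the 437 tags below before. Some abundant tags of the cellulose-containing media had relatives that start alike and end in A. For CATGGCTCAAAGAACCACTTT, the forms that begin with CATGGCTCAAAGAA and end in AAAA made up 25.9% of the copies of the family in 114-2 cellulose-wheat bran (exact 95% binomial interval 24.0 to 27.8) and 24.4% in JU-A10-T cellulose-wheat bran (24.0 to 24.8). In cellulose they made up 2.42% in 114-2 (1.72 to 3.30) and 7.52% in JU-A10-T (7.14 to 7.91). For CATGGTTGTCTTATCAGCAAC the shares were 56.8% (53.8 to 59.7) and 48.1% (47.6 to 48.7) in cellulose-wheat bran, and 7.35% (3.97 to 12.2) and 22.4% (21.4 to 23.4) in cellulose. In JU-A10-T glucose the shares were 8.21% (5.48 to 11.7) and 26.2% (21.5 to 31.3). For CATGCGCATCAAATGCAAAGT, hardly listed in 114-2, the JU-A10-T shares were 13.8% (13.4 to 14.2) in cellulose-wheat bran, 6.02% (5.56 to 6.51) in cellulose and 10.6% (8.98 to 12.3) in glucose. In the 5 cases where both media gave a share in a family and strain, the A-ending share was higher in cellulose-wheat bran than in cellulose by more than counting error. Over all tags, copies that end in 8 or more A made up 1.52%, 0.488% and 2.44% in 114-2 glucose, cellulose and cellulose-wheat bran, and 3.47%, 1.43% and 6.87% in JU-A10-T. These families were chosen after their values were seen.

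Tags that begin with CATGTCGGAC would make up 0.0244% of copies if bases were uniform, and made up from 0.156% to 2.53%. In JU-A10-T glucose 77.3% of these copies went on with TGTA, and TCGGACTGTA is, as background, the reverse complement of the end of the standard adapter joined to NlaIII sites in this kind of library. Without them, 906 tags in place of 933 were lower in JU-A10-T cellulose than glucose.

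The 93 pairs of tags that differ by 1 base may mark base differences between the strains, a hypothesis found and tested on the same data. Writing the tags backwards gave 0 pairs but decides nothing, since unrelated tags would give 0.000444 pairs by chance. Near-identical genes of one genome are argued against as the whole account, since pairs within the strains numbered 10 (upper 95% Poisson limit 18.4). Sequencing errors of the counterpart are argued against for these 93 pairs. An error needs its more abundant parent in the same library. Each form had 5 or more CPM in every library of its strain, where its counterpart, by the choice of pairs, was under 1 CPM. Errors of some other tag were not tested. The question cannot be judged further by the share of the counterpart form. It made up at most 0.0963% of the copies in any library, in pairs defined without that library. The pairs were chosen with this form under 1 CPM in the strain's remaining libraries, which favours a low share. Base differences stay open, as no genome sequence was used here. If all 93 pairs were base differences, the rate would be 0.879 per 1000 bases (0.710 to 1.08, counting error only). This is over the pairs and the 6132 tags at 5 or more CPM in all 6 libraries. CPM in this paragraph are on library totals, without scaling. Pairs from near-identical genes were not taken off, and each form needed 5 CPM only in its own strain.

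A low glucose level in 114-2 of tags that answer cellulose was tested on 437 tags at least 4-fold higher in both cellulose-containing media in JU-A10-T, chosen with no use of 114-2. The pattern did not hold over this group: the median log2 ratio of JU-A10-T glucose to 114-2 glucose was -0.084 (95% bootstrap interval -0.40 to 0.20), with 95 tags at least 4-fold above and 88 at least 4-fold below. Choosing tags for a low JU-A10-T glucose level would push this median below 0, and its interval leaves that open. Among random lists matched on the JU-A10-T glucose and 114-2 cellulose levels, whose median was -1.11, the group lay at percentile 100 of 10000. Among lists matched on mean expression, whose median was 0.21, it lay at percentile 1.39. The 518 tags at least 4-fold lower in both media also lay at percentile 100 under the first matching, so that bound, though set before the result was seen, does not single out the group, and incomplete NlaIII digestion stays open. Of the 437 tags, 32 were at least 4-fold higher in both media in 114-2 too, where independent lists would share 4.13. Of the 518 tags lower in both media in JU-A10-T, 32 were lower in both in 114-2 too. Independent lists would share 80.9. Neither this count nor the 4.13 decides, as the pool of both held many tags hardly present in JU-A10-T.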
